A study of Mus musculus with 10 samples.

How the data were processed

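Hippocampi of 10 male APP/PS1 mice, a transgenic strain that deposits amyloid in the brain, were profiled by bulk RNA sequencing. Per the labels' protocols, RNA was purified from frozen tissue with a Qiagen column kit, messenger RNA was captured on oligo(dT) beads, and libraries were made with the NEBNext Ultra kit for Illumina sequencing. Capture on oligo(dT) selects polyadenylated RNA, so transcripts without a poly(A) tail are poorly represented. The setting of strand in the counting was not given in the sources used here, so reads of a gene and of a gene on the opposite strand over the same exons cannot be told apart.

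The submitters' processing notes name bcl2fastq 2.17, DESeq2 without a version, and the mouse build mm10. The aligner, the counting tool and the annotation were not given in the sources used here. The deposited table holds a signal per gene and library that is never negative, which the file's own name calls DESeq2 normalised counts, with gene symbols as identifiers and 31510 genes for 10 libraries. Per the deposited values, the authors' normalised counts sum to nearly the same total in each library, which does not show how they were scaled. Such scaling takes most genes to be equal between libraries and cannot show a change shared by all genes.

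The most frequent low value of each library was taken as the value of 1 read, and it lay between 0.882 and 1.172. Dividing the total by it gave an estimated depth of 30700000 to 41500000 counted reads per library. Within a tolerance of 0.1 reads, 49.1% to 71.6% of the low values of a library were whole multiples of that value. Whole reads therefore could not be recovered. The value of 1 read may differ from gene to gene, which was not tested. The planned tests on whole reads were not run. The precision of each value is given here as the spread between mice, and no counting interval is printed.

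Samples were grouped by the treatment in the labels, with 5 mice given AAV8-GFP and 5 given AAV8-irisin. All 10 libraries were used. Genes with a value of at least 10 in at least 5 of the 10 libraries were tested, which kept 17556 genes. Values were converted to log2(value + 1), and limma 3.58.1 in R 4.3.3 was fitted with group as its factor and a mean-dependent prior variance (lmFit and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are AAV8-irisin minus AAV8-GFP on the log2(value + 1) scale, which understates changes of genes with low values. SDs of normalised counts are over the 5 mice of a group. The titles name separate mice, so p-values measure the spread between mice.

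Gene lists of cell types, neighbouring tissues, immune, neuronal, metabolic and stress programs were fixed before the data were examined, as were the groups, the tests and most alternatives. Of 36 lists, 35 were tested and the list of sex-linked genes served as a check of the labels. The lists held 570 distinct genes, 14 of them on more than 1 list. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists. The same lists were tested with the correlation estimated from these libraries, with fry, and with an exact two-sided permutation of the list score over all 252 assignments of 5 and 5 libraries. The list score is the mean of log2(value + 1) over the tested members. The smallest permutation p this design can give is 0.00794. Its 95% interval came from inverting the permutation test.

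The genes named in the text follow a rule. They include Fndc5, App and Prnp in any case, up to 15 genes of largest change in each direction past the threshold, filled to 10 by the smallest unadjusted p, the 4 members of smallest p of each list past its threshold, and the 2 members of smallest p of 9 lists chosen beforehand. Predicted genes without a given name were not named. The rule gave 74 distinct genes, some of which are not reported here.

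Positions are those of GENCODE M21, which is on mm10, and were found by gene symbol, with 97.5% of the 31510 symbols matched. Dates stood in place of 26 gene symbols, the form a spreadsheet gives to names such as those of septins, and 23 of these passed the filter. They were tested without a usable name. Of the 74 named genes, 23 have an exon that overlaps an exon of another annotated gene, which leaves their values uncertain. Besides those marked in the results, Prnp, Prlr and Rtp4 have such an overlap on their own strand. App, Bdnf, Cx3cr1, F5, Alas2, Dbp, Ermn, Rps28 and Shank1 have one on the opposite strand. Values of near-identical copies, such as Hba-a1 and Hba-a2, are uncertain because the counting could divide their reads.

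The gene test was tested on simulated data, with counts drawn for the real genes from their means, spreads and depths and 200 genes changed by known folds. Among 17583 genes it called 46% of 50 genes changed by 1.25-fold, 74% of 50 changed by 1.5-fold, 88% of 50 changed by 2-fold and 93.9% of 49 changed by 3-fold. Of 161 calls, 150 were among these genes, 5 were among 20 further genes shifted together as a list, and 6 were unchanged genes. These shares hold for many genes changed at once and for genes drawn independently of each other. With fewer changed genes the adjustment asks for a smaller p, so the shares do not give the sensitivity of the comparison of the real groups.

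Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 100, scaling by trimmed means, quantile normalisation, array quality weights, the mouse number as a block, the range of mouse identifiers as a covariate, the choroid plexus score as a covariate, a threshold of 0.1, and leaving out each library in turn. The identifier range divides mice 1 to 3 of both groups (3106 to 3117) from mice 4 and 5 (3121 to 3129). A blood covariate and the omission of pairs of libraries were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.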

Results

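Irisin is the secreted part of the membrane protein encoded by Fndc5, and is released by muscle during exercise. The study delivered it through the circulation. Male APP/PS1 mice aged 8 months were injected in the tail vein with an AAV8 vector for FLAG-tagged irisin or for GFP, a route meant to make the liver the source, and the hippocampus was dissected 2 months later. Each group held 5 mice. The normalised counts of a library summed to between 35300000 and 36600000, and between 22434 and 23035 genes had a value above 0. Estimated depth was 36600000 ± 3970000 reads in AAV8-GFP and 35500000 ± 1570000 in AAV8-irisin (SD, n = 5 each). Ddx3y, on the Y chromosome, had 1680 ± 154 normalised counts in AAV8-GFP and 1827 ± 106 in AAV8-irisin, and Xist, the RNA that silences an X chromosome in females, stayed between 3.61 and 16.4 in the 10 libraries.

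The comparison of the groups asks what peripheral irisin changed in the transcriptome of the amyloid-bearing hippocampus. No gene differed between AAV8-irisin and AAV8-GFP mice at the threshold. Fndc5 itself was not higher in the hippocampus, with 2479 ± 104 normalised counts in AAV8-irisin against 2610 ± 74.0 in AAV8-GFP, and App, the mouse gene of the amyloid precursor protein, had nearly equal means. Markers of disease-associated microglia and of blood had lower values in AAV8-irisin, and interferon-induced and choroid plexus genes had higher ones, in a set test that takes genes to be nearly independent. None of these group differences held when the correlation between genes was estimated or when the mice were permuted.

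By limma, 0 of 17556 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.942. At an unadjusted p under 0.05 there were 788 genes, 400 higher and 388 lower, where 877.8 are expected by chance. The 5 mice of AAV8-irisin did not overlap the 5 of AAV8-GFP in 141 genes, and chance gives 139.3, or 0.794% of the genes tested. The SD of log2 differences between a pair of libraries had a median of 0.363 within groups (20 pairs) and 0.364 between groups (25 pairs). The median standard error of a log2 difference was 0.0752. The first principal component held 14.2% of the variance and did not separate the groups (exact permutation p = 0.659), and the second held 13.2% (exact permutation p = 0.0476, adjusted p = 0.19 over 4 components).

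Fndc5 (ENSMUSG00000001334.9, chromosome 4, 129136999 to 129144593, plus strand) had a log2 difference of −0.075 with a standard error of 0.039 and a 95% interval of −0.16 to 0.0077, and 4 of 5 AAV8-irisin mice lay below the lowest AAV8-GFP mouse. App (chromosome 16, 84949685 to 85173766) had 128356 ± 3694 normalised counts in AAV8-GFP and 128612 ± 7297 in AAV8-irisin, a log2 difference of 0.0015 with a standard error of 0.038. Prnp (chromosome 2, 131909928 to 131938429), whose promoter drives the transgenes, had 68666 ± 3509 and 66856 ± 3509, a log2 difference of −0.039. The sign for App turned with quantile normalisation, with array quality weights and without AAV8-GFP mouse 1, AAV8-irisin mouse 1, AAV8-irisin mouse 2 or both of the latter, and that for Prnp with AAV8-irisin mice 4 and 5 left out. Whether transgene reads enter these values is not known.

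**Figure D1:**
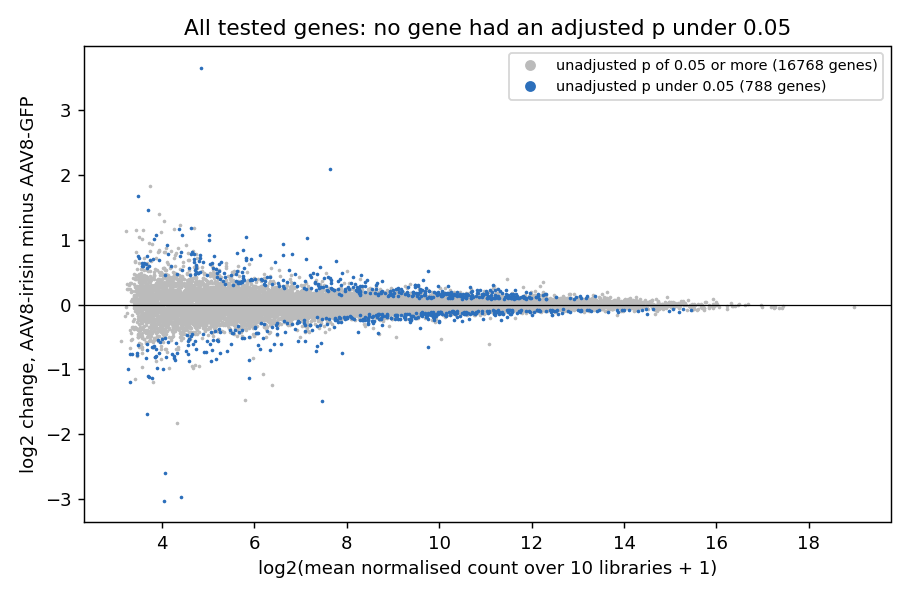
Log2 difference between AAV8-irisin and AAV8-GFP (vertical axis) against log2 of the mean normalised count over 10 libraries plus 1 (horizontal axis), 1 point for each of 17556 tested genes. Blue points are the 788 genes with an unadjusted p under 0.05, and 0 genes had an adjusted p under 0.05.

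Among named genes with higher values in AAV8-irisin, the smallest unadjusted p belonged to Bub1b, a kinase of the mitotic spindle checkpoint (chromosome 2, 118598211 to 118641591). Its normalised count was 67.3 ± 16.5 in AAV8-GFP and 128 ± 26.3 in AAV8-irisin, a log2 difference of 0.93 with a standard error of 0.19, and all 5 AAV8-irisin mice lay above the highest AAV8-GFP mouse. Rrp8, a nucleolar RNA methyltransferase, had 240 ± 24.1 and 322 ± 25.5 normalised counts, and the matrix protein gene Adamtsl3 had 51.8 ± 13.8 and 86.2 ± 8.30. The interferon-inducible helicase Ddx60 had 41.3 ± 4.35 and 70.1 ± 18.5. Log2 differences were 0.21 for Glce, an enzyme of heparan sulfate synthesis, 0.29 for Tob2, 0.30 for Polr2b, a subunit of RNA polymerase II, 0.36 for Oaf, 0.29 for the cytokinesis gene Anln and 0.73 for Ccdc146. With lower values in AAV8-irisin, Tep1, a telomerase-associated protein (chromosome 14, 50824059 to 50870560), had 300 ± 77.6 normalised counts in AAV8-GFP and 175 ± 19.7 in AAV8-irisin, a log2 difference of −0.74 with a standard error of 0.15. Bach2, a transcriptional repressor of lymphocytes, had 471 ± 66.0 and 346 ± 29.4, and the secreted synaptic protein C1ql1 had 413 ± 25.6 and 339 ± 13.6. Rac2, a small GTPase of blood and immune cells, had 113 ± 9.49 and 75.2 ± 20.1. Tfam, a transcription factor of mitochondrial DNA that also packs it (chromosome 10, 71225464 to 71238280), had 1117 ± 62.6 and 934 ± 104. The log2 differences of Trpm1, Fuz, AV039307, Usp28 and Vrk3 were −1.12, −0.24, −0.86, −0.21 and −0.18. Each of these 20 genes had an adjusted p of 0.942 by limma, so none passed. Exons of Rrp8, Polr2b, Tob2, Tep1, Bach2, Trpm1, Fuz, AV039307 and Vrk3 overlap those of genes on the opposite strand, and an exon of Glce overlaps a microRNA gene on its own strand, which leaves these values uncertain.

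Of 23 tested genes of disease-associated microglia, the state that gathers at amyloid plaques, 21 had a lower mean in AAV8-irisin, with a median log2 difference of −0.12 (camera with the preset correlation, adjusted p = 7.7e-05). With an estimated correlation the list had an adjusted p = 0.826, and the exact permutation of its score gave p = 0.230 with a 95% interval of −0.40 to 0.13. Cst7, a cystatin of plaque-associated microglia, had 474 ± 115 normalised counts in AAV8-GFP and 357 ± 129 in AAV8-irisin, and the integrin gene Itgax had 162 ± 38.5 and 124 ± 37.9. The lysozyme gene Lyz2 had 546 ± 83.8 and 466 ± 64.8, and the chemokine gene Ccl6 had 219 ± 56.7 and 169 ± 39.8. In homeostatic microglia 14 of 15 genes had a lower mean, with a median log2 difference of −0.058 (camera, adjusted p = 0.0393, and adjusted p = 0.826 with an estimated correlation). Log2 differences were −0.21 for Olfml3, −0.12 for Tmem119, −0.11 for Gpr34 and −0.094 for the fractalkine receptor Cx3cr1, whose sign turned with AAV8-irisin mice 4 and 5 left out. The score of disease-associated minus homeostatic microglia differed by −0.0597 between groups (exact permutation p = 0.429, 95% interval −0.220 to 0.0921). The disease-associated median was −0.222 without AAV8-GFP mouse 2, −0.0526 without AAV8-GFP mouse 3, −0.179 without AAV8-irisin mouse 1 and −0.0595 without AAV8-irisin mouse 5, and with AAV8-irisin mice 4 and 5, the lowest of their group, both left out it was −0.0155 and the adjusted p was 0.918. The homeostatic list had an adjusted p of 0.751 without AAV8-GFP mouse 3, 0.171 without AAV8-GFP mouse 5, 0.283 without AAV8-irisin mouse 4 and 0.396 without AAV8-irisin mouse 5, with medians of −0.000631, −0.0483, −0.0357 and −0.0269. Its median was −0.111, −0.0911, −0.113 and −0.0938 without AAV8-GFP 1, AAV8-GFP 2, AAV8-irisin 1 and AAV8-irisin 3.

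The lists of complement, pan-reactive astrocytes, astrocyte identity, antigen presentation and inflammatory cytokines did not pass the preset test. Complement genes had 10 of 15 lower means and a median log2 difference of −0.064 (camera, adjusted p = 0.328), with 5880 ± 686 and 5281 ± 628 normalised counts of C4b and a log2 difference of −0.17 for C1qc. Pan-reactive astrocyte genes divided into 6 higher and 5 lower (median 0.084, adjusted p = 0.535). Gfap, the intermediate filament of astrocytes, had 27499 ± 2776 normalised counts in AAV8-GFP and 24829 ± 2375 in AAV8-irisin, a log2 difference of −0.15 with a standard error of 0.072 and an adjusted p of 0.942 by limma. Cd44, a hyaluronan receptor, had 139 ± 22.2 and 178 ± 40.4. Astrocyte identity genes had a median of −0.020 (adjusted p = 0.599), antigen presentation 0.00078 (adjusted p = 0.855), and inflammatory cytokines and NF-kB targets −0.023 (adjusted p = 0.165).

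Of 22 interferon-induced genes, 19 had a higher mean in AAV8-irisin, with a median log2 difference of 0.22 (camera with the preset correlation, adjusted p = 1.9e-04). The adjusted p = 0.826 with an estimated correlation, and the exact permutation of the list score gave p = 0.492 with a 95% interval of −0.28 to 0.79. Ifit2 had 269 ± 17.9 normalised counts in AAV8-GFP and 326 ± 41.6 in AAV8-irisin, with 4 of 5 mice above the highest AAV8-GFP mouse. Ifit3 had 264 ± 41.1 and 360 ± 133, Rtp4 had 58.8 ± 11.1 and 86.3 ± 35.8, and the ubiquitin-like modifier Isg15 had 43.8 ± 15.6 and 72.6 ± 41.0, each with only 2 of 5 AAV8-irisin mice above the highest AAV8-GFP mouse. Ifit3 has a near-identical copy and its value is uncertain. Isg15 reached 139 in AAV8-irisin mouse 1 and 85.9 in mouse 2, and 41.3 to 52.1 in the other three. Without AAV8-irisin mouse 1 the list's median was 0.0325 (adjusted p = 0.287), and without both mice 1 and 2, the highest of their group, it was −0.0278 (adjusted p = 0.0914).

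**Figure D2:**
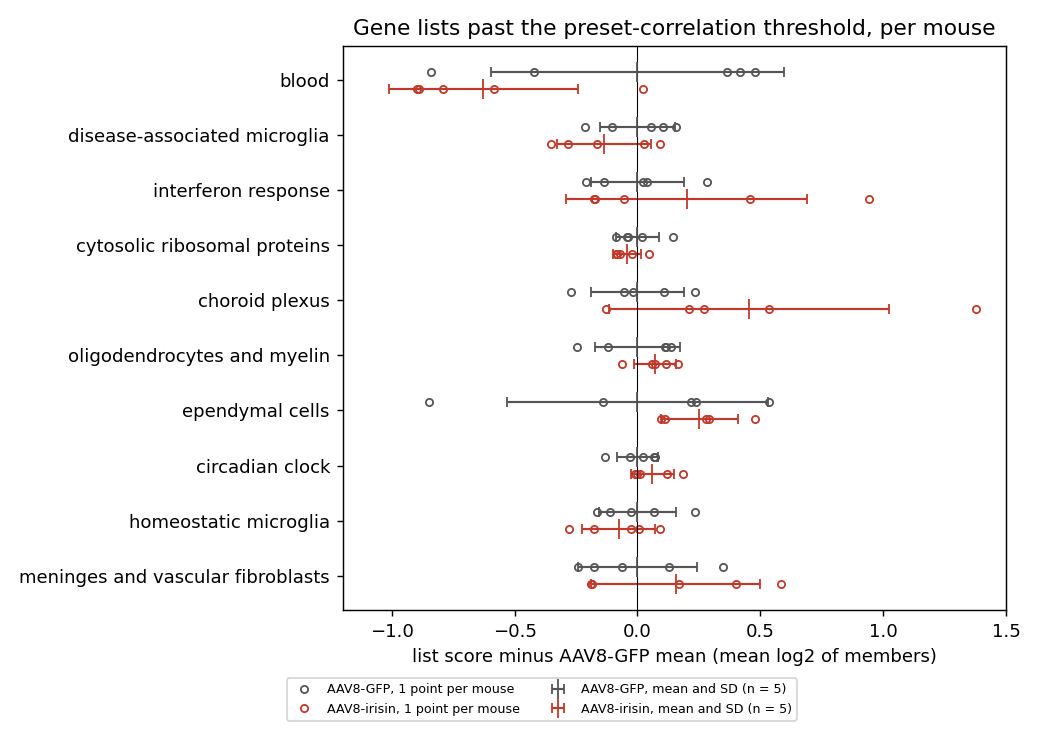
Score of each of the 10 gene lists past the threshold of camera with the preset correlation, as the mean log2(value + 1) of its tested members minus the AAV8-GFP mean (horizontal axis), with 1 circle per mouse, a vertical tick for the mean and a bar for the SD (n = 5 per group; AAV8-GFP grey, AAV8-irisin red). Groups overlap in every list, and the smallest exact permutation p among them is 0.0714, for blood.

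The blood and choroid plexus lists had the largest median differences of the 35 lists. All 5 tested red-cell genes of the blood list had a lower mean in AAV8-irisin, with a median log2 difference of −0.65 (camera, adjusted p = 7.7e-05). With an estimated correlation the adjusted p = 0.826, and the exact permutation of the score gave p = 0.0714 with a 95% interval of −1.31 to 0.20. Hbb-bt, a beta-globin, had 200 ± 68.0 normalised counts in AAV8-GFP and 122 ± 51.6 in AAV8-irisin, Hba-a2 had 1079 ± 405 and 662 ± 226, Hba-a1 had 631 ± 229 and 432 ± 123, and Alas2, the enzyme that starts haem synthesis in red cells, had 47.2 ± 19.5 and 26.9 ± 8.10. Hba-a1 and Hba-a2 are near-identical copies, so their separate values are uncertain. All 13 tested choroid plexus genes had a higher mean in AAV8-irisin, with a median of 0.42 (camera, adjusted p = 3.6e-04, and adjusted p = 0.826 with an estimated correlation; exact permutation p = 0.103). Ttr, the transthyretin gene that choroid plexus transcribes at very high levels, had 29.5 ± 18.0 and 369 ± 650 normalised counts, and reached 1528 in AAV8-irisin mouse 4. Coagulation factor gene F5 had 28.3 ± 7.56 and 47.4 ± 23.5, Prlr had 122 ± 8.22 and 184 ± 72.2, and Kl had 805 ± 89.8 and 867 ± 58.3. F5 was highest in AAV8-irisin mouse 4, as Ttr was. Prlr did not follow Ttr: it was highest in AAV8-irisin mouse 1, at 271. In AAV8-irisin mouse 3, where Ttr was 162, Prlr was 101, below every AAV8-GFP mouse. The choroid plexus median was 0.121 without AAV8-irisin mouse 4 (adjusted p = 0.0760) and 0.280 without AAV8-GFP mouse 3 (adjusted p = 0.00632).

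Of 12 ependymal genes 11 had a higher mean in AAV8-irisin (median 0.23, camera, adjusted p = 0.0162), and of 16 oligodendrocyte and myelin genes 13 did (median 0.070, adjusted p = 0.0162). Of 15 genes of meninges and vascular fibroblasts 12 had a higher mean (median 0.088, adjusted p = 0.0474). For each of these lists the adjusted p = 0.826 with an estimated correlation, and exact permutation p-values of the scores were 0.405, 0.460 and 0.429. Log2 differences were 0.53 for Ccdc153, 0.60 for Tmem212, 0.20 for Rsph1 and 0.44 for Tekt4 among ependymal genes, which serve motile cilia. They were 0.17 for the myelin gene Mog, 0.16 for Ermn and 0.13 for Ugt8a, and 0.78 for Fmod, 0.37 for the collagen gene Col1a2, 0.63 for Crabp2 and 0.13 for Mgp. Without AAV8-GFP mouse 3 the ependymal and oligodendrocyte lists both had an adjusted p of 0.713, with medians of 0.0522 and 0.00959. Other single mice also ended the ependymal call: AAV8-GFP 2 (adjusted p = 0.0577, median 0.162) and AAV8-irisin 3 (0.118, median 0.135). The oligodendrocyte call also ended without AAV8-GFP 2 (0.267, median 0.0493), AAV8-irisin 3 (0.186, median 0.0463) or AAV8-irisin 4 (0.0760, median 0.0663). The oligodendrocyte median was 0.109 without AAV8-GFP 4 or AAV8-irisin 2, and the meninges median was 0.138 without AAV8-GFP 2 and 0.183 without AAV8-irisin 2. The meninges list no longer passed without 6 of the mice, with an adjusted p of 0.166, 0.316 and 0.0953 without AAV8-GFP 1, 4 and 5 and of 0.247, 0.0630 and 0.731 without AAV8-irisin 1, 3 and 4. Its medians in those 6 omissions were, in the same order, 0.0291, 0.0805, 0.118, 0.0547, 0.0764 and 0.0356. Striatal genes had a median of 0.062 (adjusted p = 0.0617; exact permutation p = 0.0556), genes of neocortex and subiculum 0.057 (adjusted p = 0.165), thalamic genes 0.00029 (adjusted p = 0.743) and endothelial and mural genes −0.037 (adjusted p = 0.384).

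**Figure D3:**
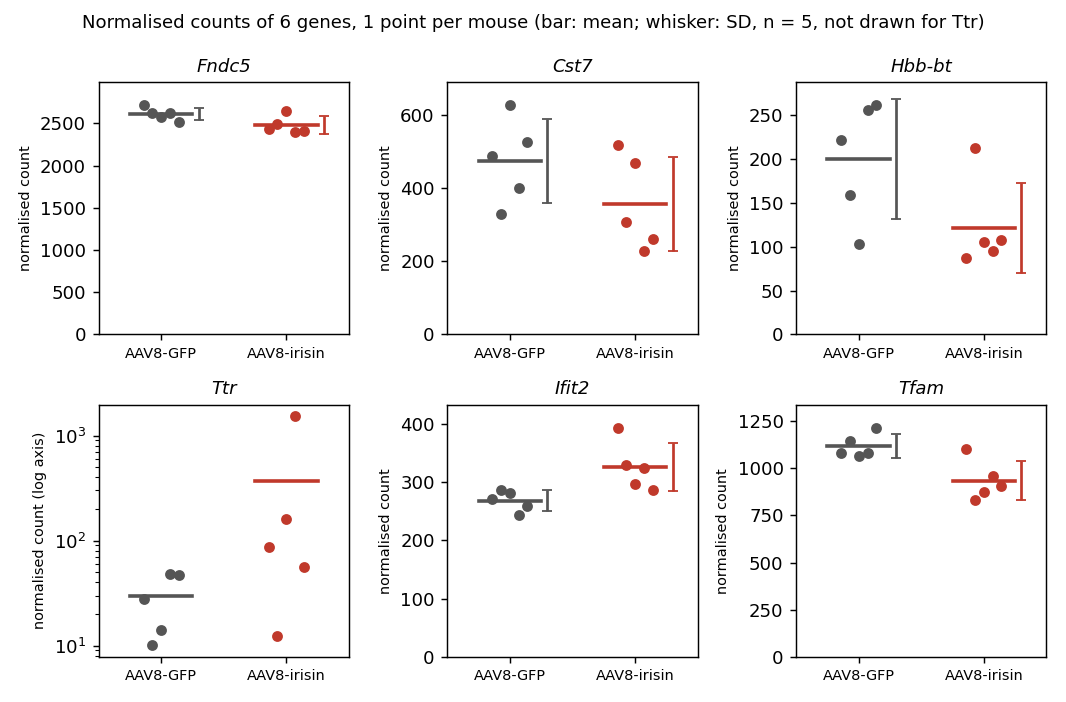
Normalised counts of Fndc5, Cst7, Hbb-bt, Ttr, Ifit2 and Tfam (vertical axes from 0, except a log axis for Ttr), 1 point per mouse, with a bar for the mean and a whisker for the SD (n = 5 per group; no whisker for Ttr). Hbb-bt is 213 in AAV8-irisin mouse 2 and 87.5 to 108 in the other AAV8-irisin mice, and Ttr is 1528 in AAV8-irisin mouse 4.

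Neuronal programs and hippocampal regions did not pass the preset test. Among 23 activity-regulated genes 16 had a lower mean (median −0.032, camera, adjusted p = 0.189). Bdnf, a neurotrophin gene linked to exercise, had 1616 ± 95.5 normalised counts in AAV8-GFP and 1463 ± 99.8 in AAV8-irisin, a log2 difference of −0.14 with a standard error of 0.055 and an adjusted p of 0.942 by limma, with 4 of 5 AAV8-irisin mice below the lowest AAV8-GFP mouse. The log2 difference was −0.14 for Nr4a3, and the list of neurotrophins and plasticity genes had 7 higher and 7 lower means (median −0.0015, adjusted p = 0.535). Excitatory synapse genes had a median of 0.0037 (adjusted p = 0.743) with a 95% interval of the score difference of −0.064 to 0.094, and the log2 differences of the vesicular glutamate transporter Slc17a7 and the scaffold Shank1 were −0.060 and −0.096. Medians were 0.026 for dentate granule cells (adjusted p = 0.328), 0.051 for CA1 pyramidal cells (adjusted p = 0.535), −0.063 for CA3 pyramidal cells (adjusted p = 0.142), 0.0034 for interneurons (adjusted p = 0.855), −0.021 for oligodendrocyte precursors (adjusted p = 0.464) and 0.0037 for adult neurogenesis (adjusted p = 0.929). The list of irisin, its integrin receptors and the PGC-1alpha axis had 5 higher and 6 lower means (median −0.060, adjusted p = 0.189), with a log2 difference of −0.26 for Tfam and −0.35 for the integrin gene Itga5. Genes of amyloid processing and clearance had 10 higher and 10 lower means (median 0.00022, adjusted p = 0.628).

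Cytosolic ribosomal protein genes had small differences in 1 direction, with 28 of 29 lower in AAV8-irisin and a median log2 difference of −0.047 (camera, adjusted p = 3.6e-04, and adjusted p = 0.826 with an estimated correlation; exact permutation p = 0.389). The log2 differences of Rpl37, Rps14 and Rps28 were −0.12, −0.067 and −0.062. Without AAV8-GFP mouse 1 the list's median was −0.0074 and its adjusted p was 0.583. Of 16 circadian clock genes 14 had a higher mean (median 0.052, camera, adjusted p = 0.0212, and adjusted p = 0.826 with an estimated correlation; exact permutation p = 0.302), with log2 differences of 0.17 for Nr1d2, 0.16 for Dbp, 0.090 for Clock and 0.10 for Per1. The circadian list had an adjusted p of 0.376 without AAV8-GFP mouse 3, 0.146 without AAV8-irisin mouse 4 and 0.378 without AAV8-irisin mouse 5, with medians of 0.0243, 0.0415 and 0.0124. Its median was 0.0842 without AAV8-irisin mouse 2. Genes of oxidative phosphorylation had a median of −0.020 (adjusted p = 0.328), the mitochondrial genome −0.034 (adjusted p = 0.165), glucocorticoid response 0.060 (adjusted p = 0.165), unfolded protein response and heat shock −0.025 (adjusted p = 0.535) and cholesterol synthesis −0.015 (adjusted p = 0.535). The mitochondrial share of all counts was 4.98 ± 0.454% in AAV8-GFP and 4.86 ± 0.121% in AAV8-irisin.

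Over the 35 lists, 6 were higher and 4 lower in AAV8-irisin by camera with the preset correlation, 0 by camera with an estimated correlation, 0 by fry (smallest adjusted p = 0.908) and 0 by exact permutation of the scores (smallest p = 0.0556, adjusted p = 0.886). Estimated correlations within the 10 lists were 0.261 to 0.858, against the preset 0.01. Adjusted over the list alone, Hbb-bt, Alas2 and Hba-a2 of the blood list, Tfam and C1ql1 passed and no member of any other list did, and over all genes tested no list member passed. Median, mean and test differed in sign for unfolded protein response, neurotrophins, amyloid processing, thalamus, excitatory synapse, antigen presentation and adult neurogenesis.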

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

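In groups of 5 mice, a mouse was called apart when its gap to the nearest of the other 4 passed 0.71 of the group's range. This held in 11 of 222 groups of values, where chance gives 11.1. Gene values entered the rule as log2(value + 1), while normalised counts are printed here. On that scale Ttr in AAV8-irisin mouse 4, at 1528 normalised counts, was not among the 11. The tests of blood and of choroid plexus tissue in this part were chosen after the results were seen, except the one on ventricular lining.

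AAV8-irisin mouse 2 had the red-cell transcripts Hbb-bt at 212.7 normalised counts (87.5 to 108 in the other AAV8-irisin mice), Hba-a2 at 1063 (520 to 592) and Hba-a1 at 648.7 (350 to 407). The 5 red-cell genes deviated together from their group means, with a median correlation of 0.939 over pairs of genes, as different amounts of blood left in the tissue would give. A biological effect of irisin on blood volume or red cells in the brain was not tested and stays open. Chance is not excluded for the group difference, since the exact permutation of the blood score gave p = 0.0714.

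AAV8-irisin mouse 4 had F5 at 89.31 normalised counts, against 34.8 to 40.1 in the other AAV8-irisin mice, and the highest Ttr. A candidate explanation of part of the higher choroid plexus list is plexus tissue carried into that 1 dissection; without this mouse the median was 0.121 in place of 0.42 (camera adjusted p = 0.0760), but it had the highest score of its group, so its omission decides nothing. In AAV8-irisin mice 1, 2, 3 and 5 Ttr was 86.2, 12.3, 162 and 56.6 (highest AAV8-GFP value 48.3) and the list scores were 5.69, 5.29, 5.95 and 5.63 (highest AAV8-GFP score 5.65), so mouse 2 was above AAV8-GFP in neither and mouse 5 in Ttr only. If dissections had differed in ventricular lining as a whole, choroid plexus and ependymal scores would deviate together. Their correlation within groups was 0.382 over both groups, too weak to decide either way. It was 0.830 in AAV8-GFP alone and 0.493 in AAV8-irisin alone, with 5 mice each. An effect of irisin on choroid plexus transcripts was not tested apart from tissue amount and stays open.

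The other such values are AAV8-GFP mouse 1 with 650.1 normalised counts of Kl (812 to 879 in the other AAV8-GFP mice), AAV8-irisin mouse 2 with 968 of the myelin lipid enzyme Ugt8a (1124 to 1154) and AAV8-GFP mouse 3 with 2753 of Cx3cr1 (2038 to 2210). AAV8-GFP mouse 3 also had a mitochondrial genome score of 16.77 (16.4 to 16.5) and a mitochondrial share of counts of 5.781% (4.70% to 4.94%). AAV8-irisin mouse 4 had a score of activity-regulated genes of 9.307 (9.56 to 9.64 in the other AAV8-irisin mice). AAV8-GFP mouse 1 had the highest score of oxidative phosphorylation genes, 12.21 (12.12 to 12.14).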

How the results depend on the processing

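The alternatives that leave out pairs of mice or add a blood covariate were chosen after seeing the data, and the others before. No gene passed an adjusted p of 0.05 in any alternative except with no filter, where 1 gene was lower and 1256 had an unadjusted p under 0.05 among more genes tested. That gene, Gm49383, was chosen after its values were seen and had an adjusted p of 0.0108; it was listed at 0 in all 5 AAV8-irisin mice and lay between 2.66 and 13.9 in AAV8-GFP, near the floor. The smallest adjusted p of the other alternatives was 0.116 (without AAV8-irisin mouse 3) to 1.00. Leaving out each mouse in turn gave 609 to 1098 genes at an unadjusted p under 0.05. Of the named genes 6 changed sign under some of the 26 settings and 0 passed under any. The planned tests on whole reads, edgeR and DESeq2, were not run, because whole reads could not be recovered.

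For the 10 lists past the preset test, 177 of 245 values kept direction and side of the threshold, 62 lost the call and 6 turned. Counts of lists higher and lower are over all lists tested, so they can include lists other than these 10. With an estimated correlation 0 lists were higher and 0 lower (adjusted p = 0.826 for each of the 10), and with fry 0 and 0 (0.908 for each). The first of these differs from the preset test in the correlation, estimated at 0.261 to 0.858 in these lists. It also has fewer degrees of freedom, so the part of each in these losses is not known. For the other losses and turns the cause was not tested. With array quality weights 3 lists were higher (interferon response, choroid plexus and, not among the 10, striatum), and calls were lost at an adjusted p of 0.0563 for oligodendrocytes, 0.0627 for meninges, 0.0578 for ependymal and ribosomal lists and 0.0593 for the circadian list. With a mean of at least 100, 3 were higher (meninges had 0.0823), and blood, choroid plexus and ependymal lists then had too few members for a value. With the mouse identifier range meninges had 0.0564. With the choroid plexus covariate 1 list was higher (interferon response) and 1 lower (blood), while disease-associated microglia had 0.0896, homeostatic microglia and circadian clock 0.890, ependymal cells 0.873 and ribosomal proteins 0.139, and oligodendrocytes (0.926) and meninges (0.904) turned. With the blood covariate ribosomal proteins had 0.283 and meninges turned (0.261). Medians then moved from 0.228 to 0.594 for ependymal cells and from 0.070 to 0.177 for oligodendrocytes. They moved from −0.058 to −0.121 for homeostatic microglia and from 0.421 to 0.227 for choroid plexus. Without AAV8-irisin mice 4 and 5, 2 lists were higher (interferon response and ependymal cells) and 1 lower (blood), while disease-associated microglia had 0.918, oligodendrocytes 0.192, meninges 0.404, choroid plexus 0.135 and ribosomal proteins 0.499, and homeostatic microglia (0.833) and circadian clock (0.918) turned. Without AAV8-irisin mice 1 and 2, 8 lists were higher and 10 lower, of which 5 and 4 are among the 10, and the interferon list turned (0.0914).

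Leaving out each mouse in turn gave 2 to 7 lists higher and 3 to 8 lower, and adjusted p from 3.0e-08 to 0.0148 for disease-associated microglia, 4.8e-10 to 0.00146 for blood, 1.3e-07 to 0.287 for interferon response, 5.7e-07 to 0.583 for ribosomal proteins, 1.0e-05 to 0.0760 for choroid plexus, 1.4e-04 to 0.713 for oligodendrocytes, 2.1e-04 to 0.713 for ependymal cells, 0.00274 to 0.378 for circadian clock, 4.0e-04 to 0.751 for homeostatic microglia and 7.5e-04 to 0.731 for meninges. Among lists not past the preset test, the adjusted p of the list mitochondrial genome ranged from 0.00220 to 0.450, and without AAV8-GFP mouse 3 the list turned to higher and passed (0.0127). The adjusted p-values with a mouse left out are by camera with the preset correlation. That test takes genes to be nearly independent, so they do not show that a call holds. Of 625 values of uncalled lists 40 passed the threshold.

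The mouse numbers 1 to 5 of the titles were taken as names. Correlations of same-numbered mice were −0.0891 to 0.0297, and no mouse correlated best with its own number. Such correlations over 5 numbers cannot exclude a batch shared by the groups. With the number as a replicate block, 0 genes passed, 7 lists were higher and 5 lower, and meninges had an adjusted p of 0.0527.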

Other observations

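Most tests in this part were chosen after the results were seen. The exceptions are the counts of other splits for genes at an unadjusted p and for lists, and the correlation within groups of choroid plexus and ependymal scores. Relations between 6 pairs of list scores were tested across the 10 mice. Scores of disease-associated and homeostatic microglia had a Pearson r of 0.815 (permutation p = 0.00378, adjusted p = 0.0113 over 6 relations) and a Spearman rho of 0.867 (permutation p = 0.00195), with r = 0.637 without the 2 mice farthest from the median and 0.802 within groups (permutation p = 0.0128). Disease-associated microglia and complement had r = 0.738 (permutation p = 0.0147, adjusted p = 0.0295) and rho = 0.794 (permutation p = 0.00774), with r = 0.758 without the 2 farthest mice and 0.755 within groups (permutation p = 0.00837). Disease-associated microglia and pan-reactive astrocytes had r = 0.525 (permutation p = 0.121, adjusted p = 0.140) and rho = 0.430 (permutation p = 0.220), with r = 0.674 without the 2 farthest mice and 0.807 within groups (permutation p = 0.0141), so the pooled relation did not pass while the within-group r had a low unadjusted p.

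The strongest relation joined ependymal and oligodendrocyte scores, with r = 0.933 (permutation p = 3.0e-05, adjusted p = 1.8e-04) and rho = 0.939 (permutation p = 1.8e-04), r = 0.752 without the 2 farthest mice and 0.928 within groups (permutation p = 1.6e-04). AAV8-GFP mouse 3 had the lowest score of both, 4.72 for ependymal cells and 11.3 for oligodendrocytes, where the other mice had at least 5.43 and 11.4. Choroid plexus and ependymal scores had r = 0.482 (permutation p = 0.140, adjusted p = 0.140) and rho = 0.733 (permutation p = 0.0206, adjusted p = 0.0309). Their r was 0.566 without the 2 farthest mice and 0.382 within groups (permutation p = 0.0519). Interferon and antigen presentation scores had r = 0.659 (permutation p = 0.0497, adjusted p = 0.0745) and rho = 0.370 (permutation p = 0.299), with 0.683 within groups (permutation p = 0.114). Without the 2 farthest mice r was 0.339, but they were picked as the farthest, so this does not show what the relation rests on.

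The lower disease-associated microglia list in AAV8-irisin was weighed against a lower share of all microglia and against single mice. The difference between its score and that of homeostatic microglia was −0.0597 with exact permutation p = 0.429, and its interval of −0.220 to 0.0921 holds both 0 and the whole difference of the list, so a lower share of microglia and a shift of their state cannot be told apart with 5 mice per group. Without AAV8-irisin mice 4 and 5 the median was −0.0155, but they were picked as the lowest of their group, so this decides nothing. They are also the AAV8-irisin mice of the higher identifier range. AAV8-GFP mice 4 and 5, of the same range, had list scores of 10.18 and 10.39 (10.07 to 10.44 in the other AAV8-GFP mice). Without AAV8-irisin mouse 4 or 5 alone the median was −0.0901 and −0.0595 (adjusted p = 0.0101 and 0.0148 by camera with the preset correlation). That test takes genes to be nearly independent, while the correlation within this list was estimated at 0.610. These p-values therefore do not show that the difference holds. Chance is not excluded for the lower list, since the exact permutation of its score over all mice gave p = 0.230. An effect of irisin on microglia in some of the mice stays open and was not tested.

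Other splits of the 10 libraries into 5 and 5 were compared with the real one over 100 splits, the real one included. With 0 genes at an adjusted p under 0.05 in the real split and 2 at most in another, all 100 give at least as many by necessity, so that count decides nothing. At an unadjusted p under 0.05, 43 of 100 splits gave at least the 788 genes of the real split, and the highest other count was 1907. At least 10 lists passed the preset camera test in 62 of 100 splits, with a median of 11 and at most 22 lists in the others. Chance is not excluded for the genes at an unadjusted p or for the lists.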
